A study of Chlamydomonas reinhardtii with 14 samples.

How the data were processed

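RNA-seq libraries of Chlamydomonas reinhardtii were made from 14 groups of cells, 1 library per group, in 4 experiments on the day cycle, iron, copper and the sexual cycle. Per the labels, 12 libraries were depleted of rRNA with a RiboZero kit for plant leaf and 2, the poly-A libraries of the iron experiment, were selected for poly-A. Whether cultures were pooled is not stated.

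The deposited tables hold FPKM per gene with lower and upper confidence bounds and a status for each library, per the file headers. The confidence level of the bounds and the scaling between the libraries of a table are not stated. Per the submitters' processing notes, STAR 2.4.0j, SAMtools 1.3 and Cuffdiff 2.0.2 were used. The deposited GFF3 annotation, whose numbers are coordinates in nucleotides (a unit of the kind other), gave gene positions and lengths; it joins the nuclear v5.5 gene models with chloroplast and mitochondrial models. Each table lists 17824 entries, of which 17741 are nuclear, 75 chloroplast and 8 mitochondrial, and 2891 nuclear entries carry a symbol. A combined table repeats the 14 FPKM columns of the 4 experiment tables with equal values, so only the experiment tables were used, and 0 per-sample columns belonged to no sample.

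The values of both copies of psbA and of I-CreI were summed, and the 3 exon entries of psaA were averaged by length, which left 70 chloroplast protein-coding genes; the tscA small RNA gene was set apart. Ratios were taken only within a table, on FPKM plus a pseudocount of 1, over genes with a mean FPKM of at least 1 in the libraries compared. A log2 ratio of 1 either way, which is 2-fold, was the size rule. Each group has 1 library, so no test between groups was run. The gamete comparisons of the mating types were kept apart and not analysed as pairs. Comparisons were rRNA-depleted against poly-A with and without iron, iron-free against iron-replete in both library types, copper-free against copper-replete, start of light against end of dark, gamete against vegetative in each mating type, zygote against the mean of both gametes, post-germination against the mean of both vegetative libraries, and mt+ against mt- in vegetative cells and gametes. Groups, comparisons, gene lists, the rule for named genes and the main settings were chosen before the data were examined.

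Named genes were the 4 highest and 4 lowest organelle genes and the 5 highest and 5 lowest nuclear genes with a symbol, at a mean FPKM of at least 10, with members of the lists that belong to a comparison. For the library types and for the mating types, both comparisons were ranked jointly, genes needed the minimum and the same sign in both, and the rank was by the smaller absolute ratio. All 129 genes named by the ranking had an OK status in each library, 0 having another.

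Of 33 gene lists, the chloroplast lists held the genes of photosystem I (4), photosystem II (15), the cytochrome b6f complex (5), the ATP synthase (6), the large subunit of Rubisco (1), the ribosome (18), the RNA polymerase (5), the light-independent protochlorophyllide reductase (3) and others (9). The mitochondrial lists held complex I (5), cob and cox1 (2) and rtl (1). The nuclear lists held iron genes (11), copper genes (12), the small subunit of Rubisco (2), light-harvesting proteins (20), photoprotection (10), photosystem subunits (20), chlorophyll synthesis (10), carbon concentration (9), nitrogen assimilation (17), mt+ gamete genes (3), mt- gamete genes (0), gamete genes of both mating types (4), zygote genes (6), factors for chloroplast mRNAs (10), the plastid ribosome (35), the cytosolic ribosome (66), the mitochondrial ribosome (36), the respiratory chain (58), the cell cycle (14), histones (69) and intraflagellar transport (15). A list with at least 3 measured members got a percentile of its median among 10000 random lists of the same size from the same genome, matched on mean expression in 20 bins for nuclear and 3 for chloroplast genes and drawn with replacement in large pools. The percentile describes these libraries and is no test between groups. Medians carry a 95% interval over genes.

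Organelle shares were taken of the summed FPKM of protein-coding genes. Correlations are Pearson and Spearman coefficients across genes.

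The depth of each library was estimated, a step chosen after the data were seen, from the spacing of low FPKM values of genes of at least 3000 nt, which are whole multiples of the value of 1 fragment. Multiples up to 10 were tried with a tolerance of 0.1, and a depth was accepted where at least 75% of values were whole multiples. This held for 10 libraries, with shares of 78.8 to 90.3%, and for none of the 4 diurnal and copper libraries, whose highest share was 41.1%. Floors of genes listed at 0 are 3 fragments at the estimated depth. Counting error was simulated from these depths in 20 draws per comparison.

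Alternatives were a pseudocount of 0.1, a minimum mean FPKM of 10, no minimum, FPKM rescaled by the median ratio of each library to the geometric mean over nuclear genes, shares over all features, and shares without the 10 most abundant genes. Added after the data were seen were a minimum of 20 estimated fragments, chloroplast entries as deposited, gamete comparisons with each library scaled to the summed FPKM of protein-coding genes, and the zygote and post-germination comparisons without each of their gamete or vegetative libraries. A count was called close to the main one within a ratio of 1.5, a share within 1%, and a median or correlation within the 95% interval of the main value, which is wide where few genes were measured.

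The size rule was tested on simulated data with the iron comparison of the rRNA-depleted libraries, with counting error as the only source of variation. Only genes that reached the expression minimum were counted. The rule passed 0 of 49 genes changed 1.5-fold, 27 of 49 changed 2.5-fold, 42 of 45 changed 4-fold and 42 of 42 changed 8-fold. It also passed 2 of 9589 unchanged genes. Of 40 lists shifted by a log2 ratio of 1, all 40 fell outside the central 95% of random lists, and 0 of the unshifted lists did. These shares do not cover variation between cultures or shallower libraries. Depths simulated as exact counts at the estimated step were recovered within 1.69%, which tests the search and not the assumption of a step. Computations used Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9.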

Results

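RNA was sequenced from 14 libraries of the green alga Chlamydomonas reinhardtii, 1 per group, so no group has a replicate and no difference below carries a p-value. The gamete comparison was made separately in each mating type. The libraries sampled transcripts of the chloroplast, the mitochondrion and the nucleus in 4 experiments. The diurnal experiment held a library from the end of the dark period and another from 1 h into the light, in strain CC-4351. In the iron experiment, strain CC-4532 grew with iron or for 4 h without it, and each condition was sequenced after rRNA depletion and after poly-A selection. The copper experiment compared growth with and without copper. The sexual experiment followed vegetative cells and gametes of both mating types, the zygote 1 day after the cross, and cells after germination.

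Depth, as estimated from the steps between low FPKM values, was 28.3 and 28.4 M (mega) fragments in the iron-replete and iron-free rRNA-depleted libraries and 13.9 and 13.6 M in the poly-A libraries. In the sexual experiment it was 9.30 M for the mt+ vegetative library, 1.43 M for mt- vegetative, 6.35 M for mt+ gamete, 2.88 M for mt- gamete, 8.64 M for the zygote and 7.14 M after germination. The depth of the diurnal and copper libraries is unknown. Floors cover counting error only and the 95% interval of a median covers the spread between genes only, so neither covers variation between cultures. A gene is said to rise or fall where its log2 ratio of FPKM + 1 reached 1 either way at a mean FPKM of at least 1, which is a rule of size and understates the change of low genes. Nuclear genes named as the highest or lowest have a symbol and a mean FPKM of at least 10. In the iron and sexual tables the deposited bounds of changed nuclear genes overlapped in each comparison. The bounds are wide there. Over genes of at least 10 FPKM, the upper bound lay a median of 104 to 105% above the FPKM in the iron libraries. In the sexual libraries it lay 121 to 123% above. Overlap of bounds this wide does not show that a change is absent. Positions are those of the nuclear v5.5 gene models and the organelle models of the deposited annotation. Shares and levels named across the 4 experiments come from separate deposited tables and were not turned into ratios.

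In the median rRNA-depleted library, transcripts of the organelles made up about as much of the summed FPKM as those of the nucleus. Over the 12 rRNA-depleted libraries the chloroplast and mitochondrion together took a median of 51.6% of the protein-coding FPKM, from 33.9% in the copper-replete library to 69.5% in the zygote. The mitochondrion alone took between 0.583% and 2.32%. In the poly-A libraries both organelles together took 0.0908% with iron and 0.0564% without. The psbA gene, for the D1 protein of photosystem II, was the most abundant chloroplast transcript in each library except the iron-free poly-A library, where I-CreI, a homing endonuclease gene, was higher. With the 10 most abundant genes of each library left out, the median share of the rRNA-depleted libraries was 23.6%.

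**Figure D1:**
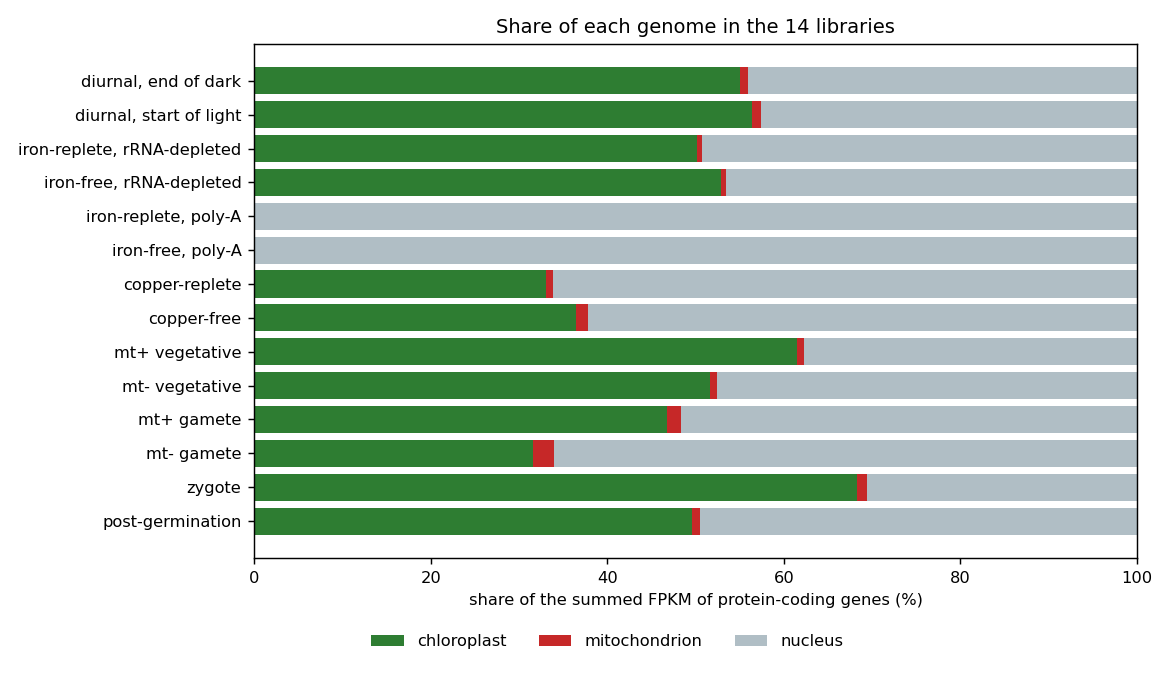
Share of the summed FPKM of protein-coding genes (x axis, percent) that fell to the chloroplast, the mitochondrion and the nucleus in each of the 14 libraries (y axis). The zygote library had the highest organelle share, 69.5%, and the 2 poly-A libraries the lowest, 0.0908% and 0.0564%.

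The first comparison asked how the library method changes what is seen of each genome, in the iron experiment. All 70 chloroplast genes and all 8 mitochondrial genes were higher after rRNA depletion than after poly-A selection, with and without iron. The median chloroplast log2 ratio was 10.23 with iron (95% interval over genes 9.48 to 10.74) and 10.70 without it (9.55 to 11.51), and the mitochondrial medians were 5.37 and 6.11. The psbA gene went from 8.04 FPKM (both copies summed, which counts shared reads once only if they were divided between the copies) after poly-A selection to 272139 after depletion in iron-replete cells, and rbcL, for the large subunit of Rubisco, from 2.2 to 81804. The atpA gene of the chloroplast ATP synthase had log2 ratios of 12.86 and 13.29. The short ycf12 gene, at 219 nt, was listed at 0 in both poly-A libraries and at 9239 and 16214 FPKM after depletion, with and without iron. Mitochondrial genes of the respiratory chain had smaller ratios, such as nad6 (4.38 and 5.45), nad1 (5.19 and 6.26) and cob (5.24 and 6.18). The chloroplast orf528 (5.73 and 4.80) was also among the lowest. Below the mean FPKM of 10 for named genes, the chloroplast orf854 (3.45 and 2.75) and orf202 (1.76 and 2.17) were lower still. The mitochondrial rtl stood at 7.69 and 8.10. Of the 70 chloroplast genes 63 lay below 1 FPKM, the pseudocount, in the poly-A library with iron and 68 in that without, so their ratios are understated and their order mostly follows the level after depletion.

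Among nuclear genes the histones stood out, whose replication-dependent transcripts largely lack a poly-A tail. All 67 measured histone genes were higher after depletion with iron and all 66 without, with medians of 3.94 and 3.52. The linker histone HON1 went from 0.0829 to 90.2 FPKM with iron, and HBV1 (5.87 and 6.19), HTR40 (5.54 and 5.82), HFO39 (5.42 and 5.47) and HTB37 (5.18 and 5.32) were among the highest in both comparisons; near-identical histone copies can share reads. The lowest nuclear ratios were those of QCR10 (-3.81 and -3.99) and QCR9 (-3.10 and -3.01), subunits of respiratory complex III, ATP15 (-3.06 and -2.88), the copper chaperone gene ATX1 (-2.73 and -2.87) and LCI30 (-3.02 and -2.69). Of the 58 nuclear genes of the respiratory chain, 11 were higher and 14 lower with iron, with a median of 0.23, which turned to -0.58 after rescaling. Cytosolic ribosomal protein genes had a median of 1.65 with 60 of 66 higher, and nuclear genes of the plastid ribosome a median of 0.99 with 17 of 35 higher, which rescaling reduced to 0.16 and 3.

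The median of all nuclear genes itself lay at 0.55 with iron and 0.66 without. Rescaling each library to its median nuclear ratio shifted the log2 ratios by -0.83 and -0.79. With iron, 3049 nuclear genes were higher and 946 lower as deposited, against 1032 and 2056 after rescaling; without iron, 3086 and 592 became 834 and 1463. Relative to the nuclear median, the histone list lay at 3.40 with iron, the cytosolic ribosome at 1.10, the plastid ribosome at 0.44, light-harvesting proteins at 1.32 and the respiratory chain at -0.32. Across 8345 nuclear genes measured in both conditions, the ratios with iron and those without had a Pearson correlation of 0.87, genes not being independent replicates.

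The iron comparison asked which transcripts change after 4 h without iron, and whether both library types show it. Genes of iron uptake were higher without iron in both, and genes of the carbon-concentrating mechanism with them. FRE1 (Cre04.g227400.v5.5), a ferrireductase, went from 0.869 to 419 FPKM in the rRNA-depleted libraries and from 0.195 to 302 in the poly-A libraries. IRT1, a metal transporter gene on chromosome 12 at 5444196 to 5447896, rose by log2 ratios of 6.76 and 6.73, and FEA2, for a secreted iron-assimilatory protein, by 4.88 and 5.23. Of the 11 measured genes of the iron list, 10 rose and none fell in the rRNA-depleted pair, with a median of 2.19, and 9 of 10 rose in the poly-A pair, with a median of 2.2; both medians were above those of all 10000 expression-matched random lists, a percentile of 100. The exception in the rRNA-depleted pair was FSD1, a superoxide dismutase gene, at 0.62.

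All 9 measured carbon-concentrating genes rose after rRNA depletion (median 4.37), and 6 of 9 after poly-A selection (median 3.07). Among them were LCI1 (7.44 and 6.68) and CAH1, the periplasmic carbonic anhydrase, which went from 47.1 to 2199 FPKM after depletion. Light-harvesting genes had medians of 0.70 and 1.00, with 5 and 10 of 20 higher. The near-identical photoprotection genes LHCSR2 and LHCSR3, which can share reads, rose by 4.86 and 4.78 after depletion. Lowest in both pairs were ACA3 (-2.80 and -4.71), CST1 (-2.04 and -3.28), NOP1 (-2.00 and -1.98), PHC5 (-2.23 and -1.91) and the flagella-associated FAP24 (-1.93 and -1.82). The copper list had medians of 0.51 after depletion and -0.64 after poly-A selection.

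Chloroplast genes had a median log2 ratio of 0.12 (95% interval -0.07 to 0.25) without iron in the rRNA-depleted pair, where 4 rose and 1 fell, the faller only without rescaling. These were psbI (3.96), petL (3.39), psbT (1.79) and psaJ (1.39), all short entries of 224 to 518 nt, and orf528 (-1.01), named after their values were seen. The mitochondrial median was 0.13, and none of its 8 genes passed the size rule. In the poly-A pair, where only 6 chloroplast genes reached the expression minimum, psbA (-1.47), rbcL (-1.14) and the mitochondrial nad6 (-1.03) fell, likewise named after their values were seen. Of the nuclear genes, 383 rose and 595 fell after depletion, and 392 rose and 1115 fell after poly-A selection. The ratios of the 2 library types had a Pearson correlation of 0.73 and a Spearman correlation of 0.72 across 7218 genes. Both types showed a rise for 214 genes, where 16.6 would overlap in independent lists, and a fall for 308, against 69.5. Since both types sample the same conditions, the lists are not independent, and the overlap is no replicate check.

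Copper-free growth, the question of the copper comparison, went with higher levels of most genes of the copper list. CYC6 (Cre16.g651050.v5.5, chromosome 16 at 1238558 to 1240109), for the cytochrome that replaces plastocyanin, had the highest ratio among nuclear genes with a symbol, 9.24, from 0.885 FPKM (deposited bounds 0.234 to 1.54) to 1139 (877 to 1401). The tetrapyrrole enzymes CPX1, a coproporphyrinogen oxidase, and CRD1, of the cyclase step of chlorophyll synthesis, rose by 4.08 and 3.51, while CTH1, the counterpart of CRD1, fell from 152 to 40.5 FPKM. Of the 12 genes of the copper list, 9 rose and 1 fell, with a median of 2.49 (percentile 100). Risers included the copper transporters CTR1 (1.95), CTR2 (3.18) and CTR3 (2.71), ferredoxin FDX5 (2.51) and the hydrogenase HYDA1 (1.24).

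Other nuclear genes of high ratio without copper were GOX17 (4.28) and HPD1 (3.82). The lowest were the small heat shock genes HSP22E (-4.07) and HSP22F (-3.68), with SSS2 (-1.34) and SBD1 (-1.2). In the iron list 5 of 9 measured genes rose (median 1.03), among them IRT2 (3.43) and FRE1 (2.27). Nuclear respiratory genes had a median of 0.41 with 5 of 58 higher, and nuclear genes of the mitochondrial ribosome a median of 0.25 with none past the size rule. In the mitochondrion cox1 (Mt at 5042 to 6691), for a subunit of cytochrome oxidase, rose from 1251 to 5423 FPKM (deposited bounds 400.2 to 2102 and 3739 to 7107), and rtl rose by 1.13. In the chloroplast, ycf3, needed for photosystem I assembly, rose by 1.5 and petG of the cytochrome b6f complex by 1.35. The lowest organelle ratios, none past the size rule, were those of nad2 (-0.07), psbZ (-0.05), atpF (-0.05) and rps7 (-0.04). The chloroplast median was 0.43 (0.38 to 0.48). Of the nuclear genes 235 rose and 160 fell, and the deposited bounds of 224 risers and 64 fallers did not overlap. The upper bound lay a median of 64.0% above the FPKM in the copper-replete library and 19.2% in the copper-free library. A faller therefore needed a larger change than a riser to have bounds apart, and these 2 counts cannot be compared.

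The diurnal comparison asked what changes when the light comes on. At 1 h into the light, genes of carbon concentration and photoprotection stood far above the end of the dark. CAH5 (7.32) and CAH4 (7.11), mitochondrial carbonic anhydrases encoded side by side and nearly alike, and the carrier CCP1 (7.19) had among the highest ratios, with MES1 (6.89) and PSBS1 (6.6), which acts in energy dissipation. PSBS1 went from 0.239 to 119 FPKM and LHCSR1 from 15.8 to 1467. Of the 10 photoprotection genes 9 rose and none fell (median 3.28, percentile 100), and of the 9 carbon-concentrating genes 6 rose (median 5.77). Those that did not pass were CAH1 (0.22), LCIB (-0.54) and LCIC (0.93).

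Chloroplast genes had a median of 0.59 (0.52 to 0.79), and 15 rose and 2 fell, with deposited bounds apart for 1 riser and 0 fallers. After rescaling 27 rose and 1 fell, with a median of 0.81. Highest were the open reading frames orf202 (3.84) and orf854 (2.58), I-CreI (3.11) and tufA, for the elongation factor of chloroplast translation, which went from 1576 to 7478 FPKM. In the cytochrome b6f complex 3 of 5 genes rose, petB (1.21), petD (1.23) and the short petL (1.65), and after rescaling petA (1.01) and petG (1.09) passed too. The genes of the light-independent protochlorophyllide reductase, which makes chlorophyll in the dark, went the other way: chlB (-1.39) and chlN (-1.2) fell and chlL stood at -0.99, while after rescaling chlN stood at -0.98 and no longer passed. The next lowest, rpoA, stood at -0.18. In the mitochondrion rtl rose by 1.72. Nuclear genes of the plastid ribosome rose in 28 of 35 cases (median 1.66), but PSRP1 fell from 56.9 to 0.481 FPKM. Nuclear genes of the mitochondrial ribosome rose in 13 of 30 cases.

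Light-harvesting genes fell in 9 of 20 cases (median -0.97), and histones in 20 of 28 (median -1.15). The light-dependent reductase gene POR1 fell from 101 to 8.43 FPKM, and PSBP1, an oxygen-evolving subunit of photosystem II, from 516 to 107. Among the lowest were also FAP291 (-5.62), HCP4 (-5.32), and PCK1 (-5.60) and ICL1 (-5.11), enzymes of gluconeogenesis and the glyoxylate cycle. Of all nuclear genes 1513 rose and 2360 fell, and the deposited bounds of 610 and 1968 did not overlap. The bounds were wider in the light library, with the upper bound a median of 67.4% above the FPKM, against 39.2% at the end of dark. A riser therefore needed a larger change than a faller to have bounds apart, and these 2 counts cannot be compared. The majority turned at a minimum mean FPKM of 10, with 685 higher and 493 lower. Rescaling shifted the ratios by 0.22 and gave 1839 and 1993. Relative to the nuclear median of -0.14, photoprotection lay at 3.42, carbon concentration at 5.91, the plastid ribosome at 1.80, light-harvesting proteins at -0.83 and histones at -1.01. The medians of nuclear photosystem subunits (-0.21), nitrogen assimilation (-0.06) and the respiratory chain (-0.15) turned to 0.01, 0.16 and 0.06 on rescaling.

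**Figure D2:**
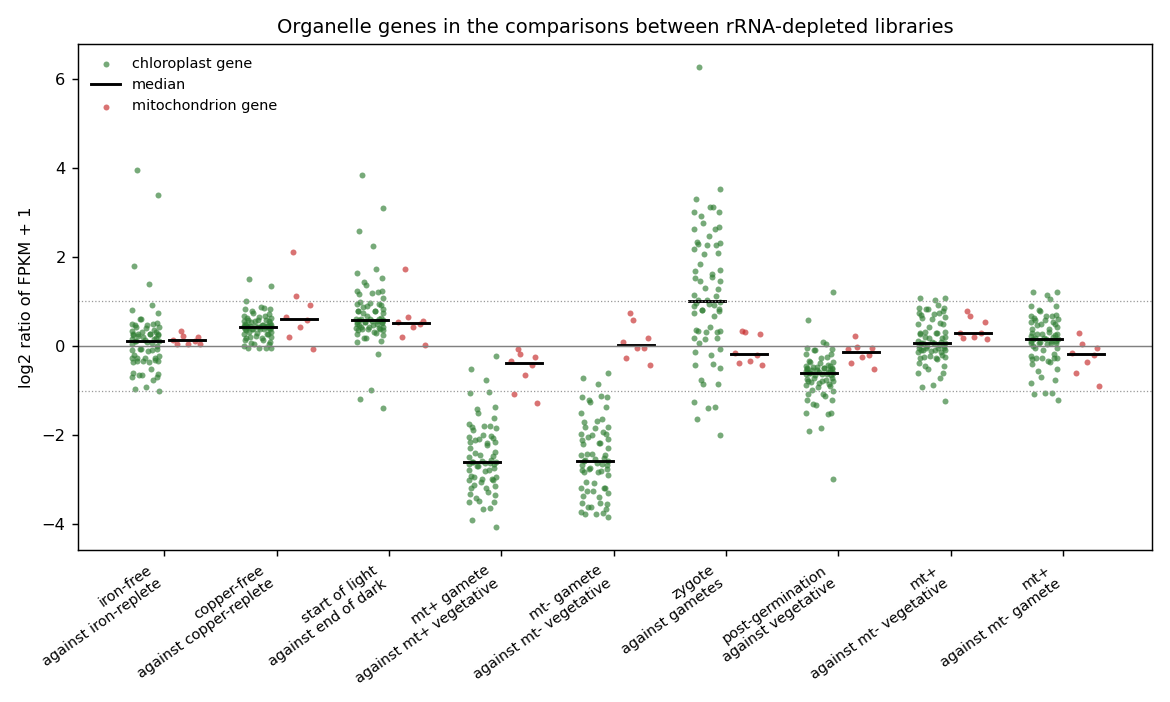
Log2 ratio of FPKM + 1 (y axis) of each chloroplast gene (green) and mitochondrial gene (red) in the 9 comparisons between rRNA-depleted libraries (x axis), with black bars at the medians and dotted lines at the size rule of 1 either way. Chloroplast medians were lowest in the gametes, -2.60 and -2.58, and highest in the zygote, 1.00.

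In gametes, which were kept without nitrogen, photosynthesis genes of the chloroplast and nucleus fell together in both mating types. Of the 69 measured chloroplast genes 66 fell in each mating type and none rose, with medians of -2.60 in mt+ (-2.78 to -2.29) and -2.58 in mt- (-2.78 to -2.19). The size of the fall depended on the scaling: with each library scaled to its summed FPKM, chosen after the result was seen, the medians were -1.3 and -1.22, with 44 and 42 genes lower. The psaB gene of photosystem I went from 12659 to 750.4 FPKM in mt+ and from 6137 to 486 in mt-. Its log2 ratios were -4.07 and -3.66. By the smaller of both falls, petB (-3.51 and -3.77), psbK (-3.42 and -3.85) and rps4 (-3.66 and -3.38) followed, and petB and psbK fell further than psaB in mt-. By group, the medians in mt+ and mt- were -3.13 and -3.58 for photosystem I, -2.73 and -2.76 for photosystem II, -2.63 and -2.64 for the cytochrome b6f complex, and -2.12 and -2.66 for the ATP synthase. They were -2.68 and -2.43 for the 18 ribosomal protein genes, -2.41 and -2.10 for chlB, chlL and chlN, and -3.01 and -2.12 for the 9 remaining listed genes. The chloroplast RNA polymerase list had the smallest fall of the chloroplast lists, with medians of -1.62 and -1.21. The deposited bounds of 1 faller in mt+ and 2 in mt- were apart. Mitochondrial genes had medians of -0.38 and 0.02, the latter of which turned to -0.01 on rescaling, and 2 of 8, nad2 and nad4, fell in mt+. Scaled to the summed FPKM, the mitochondrial medians were 0.93 in mt+ and 1.38 in mt-. The mitochondrial complex I list had medians of -0.66 and -0.06, and cob and cox1 of -0.25 and 0.46. Among organelle genes below 0 in both mating types, those with a ratio nearest to 0 in either were nad2 (-1.07 and -0.04), nad5 (-0.66 and -0.06), cemA, for an envelope membrane protein (-0.22 and -0.86), and nad4 (-1.28 and -0.27).

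All 20 light-harvesting genes fell in both mating types, with medians of -5.58 in mt+ and -5.16 in mt-. LHCB5, a minor antenna protein of photosystem II, went from 1662 to 3.14 FPKM in mt+ and from 949.6 to 4.26 in mt-. LHCBM7 (-7.20 and -6.65), whose reads can be shared with near-identical LHCBM genes, and LHCA5 (-7.30 and -6.32) followed, with the rubredoxin RBD2 (-6.24 and -6.63) and THI4 of thiamine synthesis (-5.93 and -5.98). Of the nuclear photosystem subunits 17 of 20 fell in mt+ and 17 of 19 in mt-, while PSBS1, which the list also holds, rose (2.14 and 2.76). All 35 nuclear genes of the plastid ribosome fell in both (medians -3.72 and -2.69), as did all 10 of chlorophyll synthesis (medians -3.19 and -2.10). RBCS1 (-3.30 and -2.55) and RBCS2 (-2.67 and -2.12), for the small subunit of Rubisco, fell too. Cytosolic ribosomal protein genes had medians of -0.27 and -0.69.

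Nitrogen assimilation rose in 13 of 16 genes in mt+ and 11 of 15 in mt- (medians 1.79 and 2.00, percentile 100 for both). The ammonium transporter AMT4 had the highest paired ratio, from 0.472 to 211 FPKM in mt+ and 2.19 to 332 in mt-. The urea amidolyase gene DUR1 rose by 3.54 and 3.18 and the glutamine synthetase GLN3 by 2.12 and 2.34. Also high were the permease genes XUV6 (5.84 and 5.93) and XUV1 (5.94 and 5.45), CGL41 (5.05 and 5.48) and NSG13 (5.05 and 4.65), a gene named for gametogenesis under nitrogen starvation. The iron list fell in 6 of 8 genes in mt+ and 7 of 8 in mt- (medians -2.13 and -3.01). FUS1, the mt+ fusion protein gene, stood at 14.2 FPKM in the mt+ gamete and 0.125 in the mt- gamete, and HAP2, the mt- fusogen gene, at 0.552 and 7.11. Of the list of gamete genes of both mating types, which also holds HAP2, 3 of 3 measured genes rose in mt- (median 1.94) and 1 of 2 in mt+ (median 1.09). GAS28 rose in both (2.54 and 1.94), while GLE1 was at 75.9 and 58.6 FPKM in mt+.

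Of the nuclear genes 1297 rose and 1592 fell in mt+, and 1931 rose and 1919 fell in mt-, whose vegetative library was the shallowest of those with an estimated depth. In mt+ a minimum mean FPKM of 10 left 352 higher and 869 lower. The balance in mt- depended on the setting, with 1819 higher and 1955 lower after rescaling, 445 and 971 at a minimum mean FPKM of 10, and 1631 and 1302 at a minimum of 20 estimated fragments, the last chosen after the data were seen. Scaling to the summed FPKM, chosen likewise, moved the nuclear medians to 1.00 and 1.05 and gave 6145 higher and 473 lower in mt+ and 6476 and 490 in mt-. In simulated libraries differing by counting error alone, 12 and 300 genes passed the size rule. The ratios of the mating types had a Pearson correlation of 0.78 and a Spearman correlation of 0.71 across 10689 genes. Both showed a rise for 711 genes, against 202 in independent lists, and a fall for 1135, against 264.

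**Figure D3:**
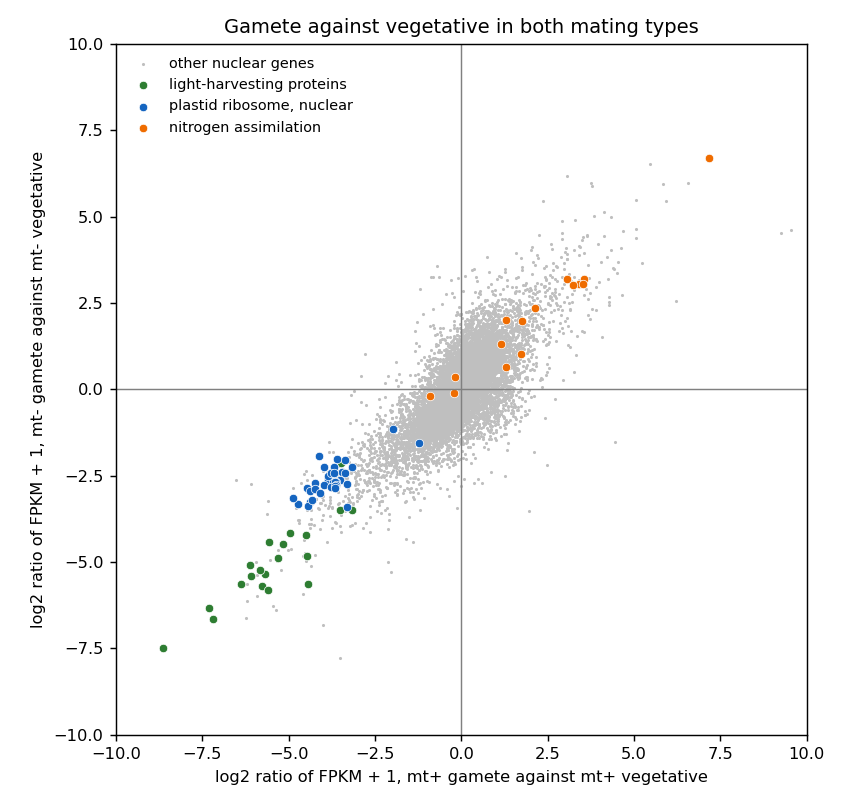
Log2 ratio of gamete against vegetative FPKM + 1 in mt+ (x axis) and mt- (y axis), 1 point per nuclear gene. Light-harvesting genes (green) lie lowest in both, with medians of -5.58 and -5.16, plastid ribosome genes (blue) lie between them and 0, and nitrogen assimilation genes (orange) have medians of 1.79 and 2.00.

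The zygote was compared with the mean of the log2 values of both gametes. In the zygote, kept without nitrogen in the dark, photosystem genes of both genomes stood above the gametes, while genes of cell division, histones and cytosolic ribosomes stood below. ZYS3, a zygote-specific gene, was at 738 FPKM in the zygote, 3.85 and 7.42 in the gametes and 6.22 and 15.7 in vegetative cells, where the latter of each pair is mt-. In the libraries of the other experiments ZYS3 stood at or below 0.44 FPKM. Why it was higher in gametes and vegetative cells of the sexual experiment was not tested. With ZYS4 (2.53) it made up the measured zygote list, whose median was 4.69; the other 4 genes of the list, ZYS1a, ZYS1b, EZY1 and EZY2, stayed below 1 FPKM in the zygote and both gametes and were not measured. Rescaling shifted the zygote ratios by 0.35. For the lists that follow, the values in brackets are medians relative to the nuclear median of -0.22. Counts of genes, ratios of single genes and the zygote list median above are as deposited. Of the 15 photosystem II genes of the chloroplast 14 rose (2.56) and of photosystem I all 4 did (2.91), with psbB going from 3547 and 2943 FPKM in the gametes to 20607. Of 20 light-harvesting genes 19 rose (3.61), LHCB5 to 374 FPKM, as did 15 of 19 nuclear photosystem subunits (2.92). All 7 measured carbon-concentrating genes rose (4.47), led by the transporter NAR1.2 (5.92).

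The highest chloroplast ratios were those of psbT (6.27), petL (3.53), psbI (3.30) and psbJ (3.13). The entries for psbT, petL and psbI are short, and those 3 also rose in the iron-free rRNA-depleted library. Lowest were rpoB2 (-2.01), rpoB1 (-1.63) and rpoA (-1.25), subunits of the chloroplast RNA polymerase, and rps2 (-1.37). Their entries are long, from 2952 nt for rpoB2 to 3363 nt for rpoB1. Across the 70 chloroplast genes the ratio fell with length (Spearman -0.56), and a length bias was not tested for these long entries. After rescaling rpoA stood at -0.91 and no longer passed, and against the mt+ gamete alone neither rpoA (-0.91) nor rps2 (-0.84) did. The chloroplast median was 1.00 (0.78 to 1.53) with 35 genes higher and 5 lower, or 46 and 4 after rescaling. The FPKM of all entries summed to 748469 in the zygote and to 474972 and 392531 in the mt+ and mt- gametes. Scaling each library to its sum would therefore lower the zygote ratios. It was not run here, and the size of the rise may depend on the scaling. No mitochondrial gene passed the size rule, and the mitochondrial median of -0.17 turned to 0.18 on rescaling.

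Among nuclear genes GOX5 (8.11) and GOX13 (7.65) had the highest ratios of those with a symbol. Histones fell in 63 of 67 cases (-2.53 relative to the nuclear median), with HON2 (-5.29), HFO18 (-5.03) and HTA21 (-4.69) lowest. Cell cycle genes fell in 13 of 14 (-1.35), such as the cyclin-dependent kinase CDKB1, from 18.5 and 25.7 to 0.582 FPKM. Cytosolic ribosomal protein genes fell in 59 of 66 (-1.74). DPD1 (-4.60) and FMG1-B, a flagellar membrane glycoprotein gene (-4.54), were also among the lowest. As deposited 1144 nuclear genes rose and 2092 fell, and after rescaling 1783 rose and 1532 fell.

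After germination, nuclear genes of the plastid ribosome and chloroplast RNA polymerase genes stood below the mean of the vegetative libraries. The medium was not that of the vegetative cultures. The former fell in 32 of 35 cases (median -1.68), and the latter in 4 of 5 (median -1.21), or 3 against the mt+ library alone. Of the ribosomal protein genes of the chloroplast itself only 4 of 18 fell (median -0.79). Chloroplast genes had a median of -0.61 (-0.73 to -0.52), with 14 lower and 1 higher. The fallers were led by I-CreI (-2.98), orf854 (-1.91), tufA (-1.84) and rpl23 (-1.53), and the riser was chlB (1.21), followed among organelle genes without passing the size rule by chlN (0.59), the mitochondrial nad6 (0.23) and psbD (0.10). Histones rose in 30 of 68 cases (median 0.84), which rested on the mt+ library: against mt+ alone 57 rose (median 1.64) and against mt- alone 12 (median 0.06).

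The glutathione transferase GST1 (5.88), HCP4 (5.04), FMG1-A (5.0), CAH1 (4.95) and the alternative oxidase AOX1 (3.56) had the highest nuclear ratios. The CAH1 value rests on vegetative levels that differ, 141 FPKM in mt+ and a listing at 0 in mt-, beside 369 after germination. SHMT2, a serine hydroxymethyltransferase gene (-3.33), TEF22 (-2.82), PCR1 (-2.81), PRX6 (-2.72) and PHC3 (-2.62) were lowest. Light-harvesting genes had a median of 0.01, which turned to -0.03 on rescaling and was -0.54 against mt+ alone and 0.52 against mt- alone. Chlorophyll synthesis fell in 4 of 10 genes (median -0.90), 7 against mt+ alone (median -1.48) and 2 against mt- alone (median -0.23). Of the nuclear genes 1787 rose and 1031 fell.

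Vegetative cells of mt+ and mt- differed in genes of cell division and of carbon concentration. In mt+ relative to mt-, cell cycle genes were lower in 11 of 14 cases (median -1.64) and histones in 49 of 67 (median -1.42). CDKB1 stood at 10.2 FPKM in mt+ and 44.7 in mt-. Histones HFO9 (-2.42), HTA20 (-2.35) and HBV1 (-2.30), the iron-assimilatory FEA1 (-4.04) and MOT42 (-2.27) had the lowest ratios. CAH1 was at 141 FPKM in mt+ and listed at 0 in mt-, at least 101-fold higher with a floor of 3 fragments at the estimated depth of that library. FAP211 (4.30), CAH2 (3.95), LCIB (3.68) and LCI9 (3.34) followed. Carbon concentration was higher in 5 of 9 genes (median 1.91), light harvesting in 12 of 20 (median 1.07) and chlorophyll synthesis in 7 of 10 (median 1.09).

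Chloroplast genes of the vegetative libraries had a median of 0.07 (-0.05 to 0.26). I-CreI (1.09), psbC (1.08) and psaB (1.04) were higher in mt+ and rpl36 lower (-1.23), while after rescaling psaB stood at 0.99 and no longer passed. Below the size rule came ycf4 (0.92), rpoB1 (-0.91), rps12 (-0.88) and rpoB2 (-0.73). Of the nuclear genes 746 were higher in mt+ and 660 lower, and after rescaling the majority turned, with 634 higher and 691 lower. Counting error alone gave 274 in simulated libraries. With a minimum of 20 estimated fragments, chosen after the data were seen, 885 genes passed.

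Between the gametes, the mt+ gamete list was higher in mt+ for all 3 genes (median 1.56), FUS1 (3.75), GSP1 (1.3) and SAG1 (1.56). GSP1 and SAG1 were low, at 2.88 and 2.79 FPKM in the mt+ gamete and 0.576 and 0.282 in the mt- gamete. GSP1 was no higher in the mt+ gamete than in mt+ vegetative cells, at 3.51 FPKM. None of the 4 symbols of the mt- gamete list occurs in the tables. LHCBM4 (3.41), NRX2 (3.27), FAP24 (3.19), SAH1 (2.96) and LCI3 (2.84) had the highest nuclear ratios. ACS1 (-4.70), MTA2, named for the mating type locus (-3.10), LHCSR1 (-2.46), PRL8 (-2.44) and FAP292 (-2.21) had the lowest. In the chloroplast psbC (1.21), tufA (1.2), psbA (1.14) and chlL (1.05) were higher in mt+, and rpl20 (-1.21), rpoB1 (-1.08), rpoB2 (-1.06) and rps2 (-1.05) lower. The chloroplast median was 0.17, and 452 nuclear genes were higher in mt+ and 314 lower.

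**Figure D4:**
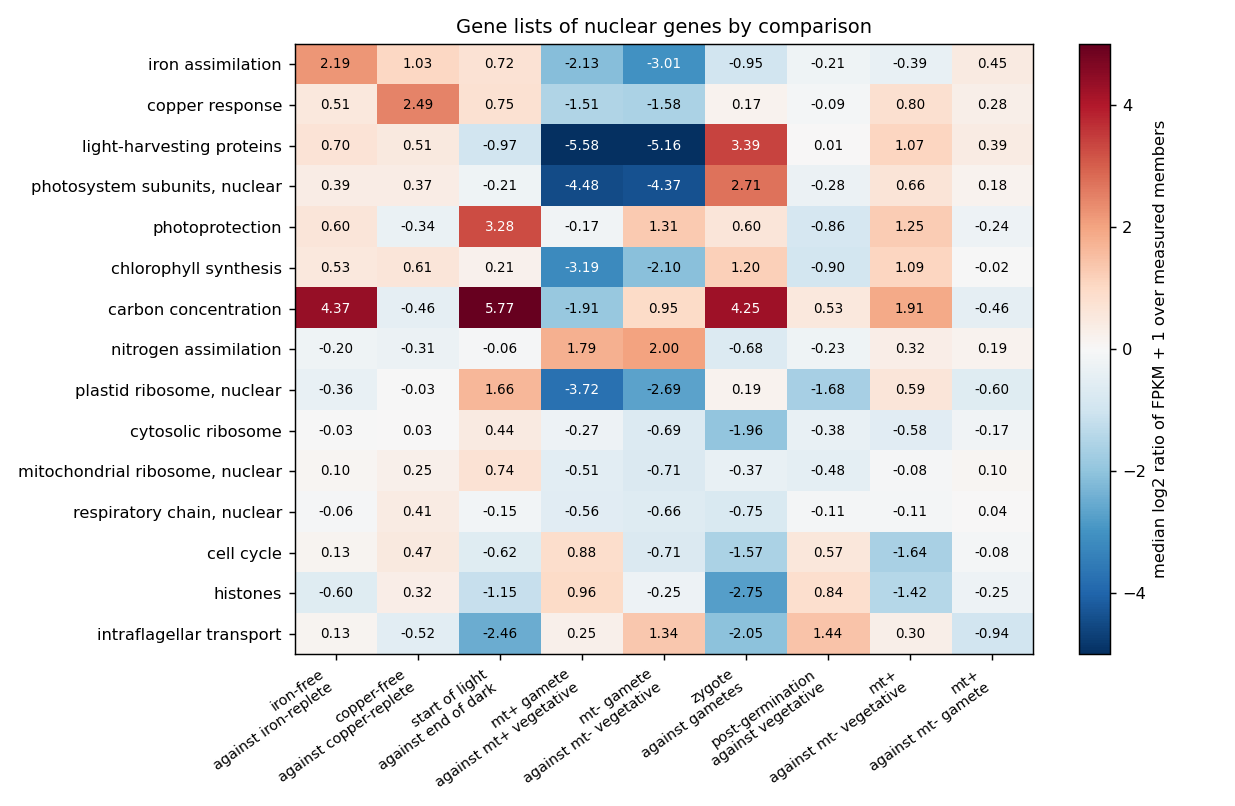
Median log2 ratio of FPKM + 1 over the measured members of 15 nuclear gene lists (y axis) in the 9 comparisons between rRNA-depleted libraries (x axis), as deposited, with red above and blue below 0. The light-harvesting list runs from -5.58 in mt+ gametes to 3.39 in the zygote; at the start of light the photosystem, nitrogen and respiratory medians change sign on rescaling.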

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

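Chosen only after the result was seen were the tests of scaling in the zygote and gamete patterns, the length tests on parts of the zygote genes, the test of abundant genes in gametes, put in place of an earlier one that could not show their effect, the test with the cell cycle list, the trend with length among chloroplast genes, the comparison with the iron-free library, and the limits that brought the next 4 results here, while the simulation of counting error was chosen after the data were seen but before its own result.

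Carbon-concentrating genes moved in opposite directions in the gametes of the mating types, with a median log2 ratio to vegetative cells of -1.91 in mt+ and 0.95 in mt-, a difference of -2.86. Cell cycle genes did the reverse, with medians of 0.88 in mt+ and -0.71 in mt-, a difference of 1.58. Genes of the copper list had medians of 0.51 in the rRNA-depleted and -0.64 in the poly-A libraries of the iron comparison, a difference of 1.14. None of these 3 differences was tested, since each group has 1 library, and list medians of at least 0.5 in opposite directions brought them here. Both gamete contrasts share their denominators with the vegetative difference between mating types weighed last. There the cell cycle list had a median of -1.64 in mt+ relative to mt-, about the size of its gamete difference with the opposite sign. The tscA gene, whose small RNA serves the trans-splicing of psaA and which the comparisons of protein-coding genes leave out, stood at 7942 FPKM in the zygote, against 995 and 1286 in the mt+ and mt- gametes and 1546 and 4204 in the vegetative libraries, and at 443 nt it is a short entry.

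In the zygote the 5 chloroplast genes with the highest ratios, psbT, petL, psbI, psbJ and psaJ, had a median log2 ratio of 3.30 to the gametes. Rescaling on nuclear genes shifts all ratios nearly alike, here by 0.35, and gave 3.62. This argues only against a scaling difference that nuclear genes share. A length bias common to all genes would raise nuclear genes too, but those of 224 to 1505 nt, the range of the 5 genes, had a median of -0.22 (2118 genes, 95% interval -0.28 to -0.18), those of 317 to 518 nt, the range of petL, psaJ and psbI, one of -0.91 (45 genes, -2.32 to -0.31), and those of 1355 to 1655 nt, around psbJ, one of -0.21 (1174 genes, -0.26 to -0.12). For psbT, at 224 nt and a ratio of 6.27, a length bias and a rise cannot be told apart, because 0 measured nuclear genes are as short. A bias confined to short chloroplast entries was not tested and stays open for psbT, petL, psbI and psaJ: these 4 of the 5 genes also rose in the iron-free rRNA-depleted library, where psbJ stood at 0.49, and the psaA entries of 216, 180 and 2027 nt had ratios of 4.49, 3.2 and 2.24. Across the 70 chloroplast genes the ratio fell with length (Spearman -0.56), and a rise of these transcripts in the zygote stays open as an untested biological explanation.

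As deposited, chloroplast transcripts fell in gametes of both mating types while mitochondrial transcripts moved less. The difference between chloroplast and mitochondrial medians, which scaling common to a library cannot change much, was -2.22 in mt+ and -2.60 in mt-. With each library scaled to its summed FPKM the chloroplast medians were -1.3 in mt+ (95% interval -1.47 to -1.04) and -1.22 in mt- (-1.43 to -0.84), so the size of the fall depends on the scaling. The mitochondrial medians were then 0.93 and 1.38. With the 10 most abundant genes of either library left out, the chloroplast medians were -1.47 (-1.66 to -1.2) and -1.46 (-1.68 to -1.02). Of the genes left out, 9 of 12 in mt+ and 9 of 15 in mt- were chloroplast genes. The test therefore cannot separate a few abundant genes from the fall itself. A fall of chloroplast transcripts relative to the others may be biological, as a hypothesis from the data that raised it. Gamete state and the absence of nitrogen go together in the design and were not separated, and a difference between cultures was not tested.

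The vegetative libraries of mt+ and mt- differed in 1406 nuclear genes, with histones and cell cycle genes lower in mt+. Counting error alone gave 274 genes, 19.5% of that number, although the mt- library was the shallowest. Reads shared between histone copies cannot account for the cell cycle genes, whose median was -1.64 beside -1.42 for histones. Whether shared reads added to the histone difference stays open, since the cell cycle genes cannot show it. A difference in the share of dividing cells may explain both lists, as a hypothesis not tested further. Strain, mating type and the state of each culture stay open, with 1 library of each.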

How the results depend on the processing

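Chosen after the data were seen were the alternatives with at least 20 estimated fragments, with chloroplast entries as deposited, with gamete comparisons scaled to the summed FPKM and with single gamete or vegetative libraries. Of 202 alternative values, which are chloroplast medians, correlations, shares and total counts without direction, 167 stayed close to the main value and 35 moved further, and 0 of the chloroplast medians changed sign. Apart from these, rescaling turned the sign of the nuclear median between library types with iron (0.55 to -0.07), in light (-0.14 to 0.03) and in the zygote (-0.22 to 0.04), and of the mitochondrial median in mt- gametes (0.02 to -0.01) and in the zygote (-0.17 to 0.18). Scaling to the summed FPKM turned the mitochondrial median in mt+ gametes from -0.38 to 0.93 and the nuclear median in mt- gametes from -0.002 to 1.05. A median counted as close inside the 95% interval of the main value, which in the poly-A iron comparison spans -1.47 to 0.75 over 6 chloroplast genes, so that the change from -0.75 to -0.14 with no minimum (70 genes) passed as close. Of 64 alternative splits of nuclear genes into higher and lower, 8 turned the majority. Rescaling did so between library types (1032 higher and 2056 lower with iron, 834 and 1463 without), in mt- gametes (1819 and 1955), in the zygote (1783 and 1532) and between vegetative mating types (634 and 691). A minimum mean FPKM of 10 did so in the light (685 and 493) and in mt- gametes (445 and 971), and scaling to the summed FPKM in mt+ gametes (6145 and 473); the cause was not tested. A minimum mean FPKM of 10 left fewer genes and so lower nuclear counts: 1344 and 1242 for the library types with and without iron, 360 and 469 for iron in rRNA-depleted and poly-A libraries, 164 for copper (121 higher and 43 lower), 1178 for light, 1221 (352 and 869) and 1416 for mt+ and mt- gametes, 1075 for the zygote, 1010 after germination, and 354 and 218 between vegetative cells and gametes of the mating types. It left no chloroplast gene in the poly-A iron comparison, which has no value there. It also gave correlations of 0.83 for iron and 0.88 for gametes.

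A pseudocount of 0.1, which enlarges the ratios of low genes by construction, gave chloroplast medians of 11.84 and 13 between library types with and without iron. Its nuclear counts were 1584 and 2413 for iron in rRNA-depleted and poly-A libraries, 817 for copper (417 and 400), and 2365 and 1345 between vegetative cells and gametes of the mating types. It counted 5 chloroplast genes in the poly-A iron comparison and gave a gamete correlation of 0.75. Chloroplast entries as deposited also gave 5 there, since a second copy of psbA and a pair of psaA exon entries then count singly.

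Rescaling changed the nuclear count between library types without iron to 2297, the chloroplast median in light to 0.81 and its count to 28 (27 higher and 1 lower). With at least 20 estimated fragments, 885 nuclear genes differed between vegetative mating types (586 higher in mt+ and 299 lower), which leaves fewer genes tested. Scaling to the summed FPKM, which raises every ratio where the sum itself is lower, as in both gametes, gave chloroplast medians of -1.3 and -1.22 in mt+ and mt- gametes, 42 chloroplast genes in mt-, and 6618 and 6966 nuclear genes. Without the 10 most abundant genes, organelle shares were 23.6% in rRNA-depleted and 0.0840% in poly-A libraries. Where no construction is named, the cause was not tested. Among the 10 libraries with an estimated depth, the mt- vegetative and mt- gamete libraries were the shallowest, at 1.43 and 2.88 M fragments.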

Other observations

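Chosen only after the result was seen were the relations of the library-type ratios to gene length and GC content.

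Genes of intraflagellar transport, which builds cilia, moved as a block in several comparisons. All 15 fell at the start of light (median -2.46) and all 15 in the zygote (median -2.05), where cells lose their cilia. They rose in 14 of 15 cases after germination (median 1.44) and in 13 of 15 in mt- gametes (median 1.34), against none in mt+ gametes (median 0.25). Between gametes they had a median of -0.94 in mt+ relative to mt-. Whether the mating types differ was not tested.

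Nuclear factors for chloroplast mRNAs stabilise, splice or translate single chloroplast transcripts. As deposited, they had smaller median changes than the chloroplast genes in gametes and the zygote, a difference not tested. In mt+ and mt- gametes, scaling to the summed FPKM moved the medians of all nuclear genes to 1.00 and 1.05. It moved those of chloroplast genes to -1.30 and -1.22. The comparison with these factors was not repeated under that scaling. As deposited, the medians of the factors were -0.35 and 0.14 in mt+ and mt- gametes and 0.04 in the zygote. Of the factors, 2 of 8 were lower in mt+ gametes and 0 of 8 in mt- gametes. At the start of light their median was 0.46, beside 0.59 for the chloroplast genes. The large subunit gene of Rubisco, rbcL, had log2 ratios of -2.08 and -2.45 in gametes and 1.46 in the zygote. Photoprotection genes had medians of -0.17 in mt+ and 1.31 in mt- gametes, and in vegetative cells of 1.25 in mt+ relative to mt-.

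Across nuclear genes the ratio of rRNA-depleted to poly-A libraries had Spearman correlations of 0.08 with gene length and 0.24 with GC content with iron, and of 0.15 and 0.20 without iron.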
